A study of Mus musculus with 16 samples.

How the data were processed

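Olfactory mucosa cells of S100a5-tauGFP mice were measured after vehicle or 2-hexanone, as GFP+ and GFP- cells of 8 pools of 3 mice, on 16 Clariom S mouse arrays made from 50 to 100 ng of RNA per sample, per the labels' protocols. The deposited values are log2 signals per probe set that the authors made with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarisation method and the annotation build are not given in the sources used here. The deposited log2 values run from 1.25 to 19.81, above the 16 of a 16-bit scanner, so an unstated transformation acts on all differences and folds.

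The table holds 28846 probe sets. Of these, 6640 control rows were left out (6546 negative and positive control, 63 spike-in and 31 manufacturer control rows), and 22206 were tested. A platform annotation table gave 1 gene symbol for 19572 probe sets and several for 0; 2634 were tested without a name here. All 19572 Entrez identifiers matched the reference gene table of assembly GRCm38.p6, which served for names, receptor (MOR) family synonyms and the order of neighbouring genes. Of 19505 named genes, 55 had more than 1 probe set and were represented by that of highest mean. No coordinates are given, since the build of the array was not given. The highest of 23 antigenomic background bins served as each array's background floor (6.16 to 7.33, mean 6.61). A high percentile of the negative control rows, a stricter measure, lay at 8.53 to 9.47 per array. It was not used, so "above background" refers to the floor alone. Where every array of the dimmer group lay under its floor, the fold is a bound ("at least"): the brighter mean against the mean of, per array, the higher of floor and value. No fold is given where both groups lay under it. Where only some arrays of the dimmer group lay above it, their number is given, with the untested difference or fold after raising the other arrays to their floor. No 2 arrays held identical values (highest Pearson r = 0.986).

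Groups and replicate numbers came from the sample titles. Tests used R 4.3.3 and limma 3.58.1 (lmFit and eBayes) with 4 group means over all 16 arrays, no covariate and 12 residual degrees of freedom, and called Benjamini-Hochberg adjusted p below 0.05. The 5 contrasts were GFP+ against GFP- in each treatment, odor against vehicle in each fraction, and the change of the GFP+ to GFP- difference with odor. Adjustment ran over all 22206 probe sets and, for the 1080 receptors (symbols Olfr with a number, no pseudogenes), over the list alone. A set of 18 gene lists (261 entries, 25 without a probe set here), the receptors and the 15 trace amine-associated receptors were fixed before the data were examined. Class I (119) and class II (939) were set afterwards from MOR numbers, with families up to 42 as class I, and 22 receptors had no class; both were then among the 22 sets adjusted together. Sets were tested with camera (correlation 0.01, or estimated) and fry. In fry's test of either direction the receptors passed in vehicle (adjusted p = 3.82e-17), but so did the unfolded protein response list (0.000538). In fry's test of 1 shared direction the receptors did not pass in vehicle (adjusted p = 0.32). The activity-dependent, signal transduction and mature neuron lists did (0.0275, 0.00508 and 0.0271). For odor in GFP+ cells the sustentacular, xenobiotic and class I sets did not pass that test (0.567, 0.567 and 0.962), nor did sustentacular markers in GFP- cells (0.854). Plots used Python 3.11.15 and matplotlib 3.10.9.

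The rule for named genes, fixed before the data were examined, took S100a5 and Omp; the 15 highest and 5 lowest receptors past the list threshold, or the 5 of lowest p if fewer than 5 passed; the 10 highest and 10 lowest other genes; and per list up to 4 members that passed and 2 that did not. The text names a part of these. Genes outside it were chosen after their values were seen: Olfr1494, Olfr195, Olfr1110, Olfr191 and Olfr193 in the sort contrasts, Olfr191 in GFP+ cells, Olfr1494, Olfr195, Olfr1110 and Camk2n1 in GFP- cells, Camk2n1 and Olfr1110 for the change of the sort difference, Npas4 in odor, and Taar5 and Taar8a. Kirrel3 in vehicle was also named outside the rule, and was not followed under the alternatives.

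GFP+ and GFP- samples of a pool share their mice, by the labels. Their deviations from the group means correlated at 0.425, 0.0749, 0.161 and 0.109 in odor and 0.352, 0.0136, 0.0516 and 0.0837 in vehicle pools 1 to 4 (consensus 0.171). Fits with the pool as a random or fixed block are given where they change a call. Other alternatives were a trended robust prior, quantile normalization over all arrays or within each fraction, arrays centred on medians, the lowest 20% or 40% of probe sets left out, array weights, the replicate number as a block, only the arrays compared, only probe sets with 1 symbol, and each pool left out. Bounds from the background floor, arrays raised to it, a batch term for replicate 1 and leaving out both replicate 1 pools were added after seeing the data.

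The tests were tried on simulated data of 22206 probe sets with 50 genes changed at each log2 size of 0.5, 1, 2 and 4. They recovered 6%, 46%, 94% and 100% for the sort in vehicle, 2%, 40%, 96% and 100% for the sort in odor, 0%, 32%, 96% and 100% for odor in GFP+ cells, 0%, 40%, 96% and 100% in GFP- cells, and 0%, 6%, 76% and 100% for the change of the sort difference. False calls numbered 5 to 11 per contrast. The simulated noise was independent between arrays and genes, without the pool, replicate or sort structure of the data, so recovery in the real data may be lower.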

Results

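Each olfactory sensory neuron expresses a single odorant receptor gene, and S100a5 is a calcium-binding protein gene whose level in these neurons follows their activity. In S100a5-tauGFP mice the promoter of that gene drives a green fluorescent reporter, so neurons with recent activity can be sorted as GFP+ cells. The comparison asked which receptor transcripts become enriched in GFP+ cells when mice inhale 2-hexanone, a small ketone. In all, 24 mice of both sexes, 7 to 12 weeks old, spent 40 h singly in chambers supplied with clean air at 3.1 L per min. From 26 h on, pulses of 2-hexanone (odor) or of filtered air (vehicle) lasted 10 s and came every 20 min. Dissociated olfactory mucosa from 3 mice made a pool, each of the 8 pools was sorted into GFP+ and GFP- cells, and 4 pools per treatment gave 16 Clariom S arrays in 4 groups of 4. The highest deposited log2 value, 19.81, lies above the 16 bits of a scanner, so the scale had been transformed in an unstated way, and all log2 differences and folds here are on that scale. Array medians were 5.70 to 5.76 in GFP+ and 6.06 to 6.12 in GFP- samples, and the number of arrays limits the precision of every value.

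The first comparison asked which transcripts separated the sorted fractions when no odorant was added. In vehicle, GFP+ cells had more of many odorant receptors and of 7 of 13 activity-dependent neuronal genes (2 were lower), and less of many immune, progenitor, supporting and immature neuronal transcripts. S100a5 was 2.60-fold higher in GFP+ cells (log2 difference 1.38 ± 0.25 SE, n = 4 pools, adjusted p = 0.000514), and all 4 GFP+ arrays lay above all 4 GFP- arrays. Omp, the marker of mature olfactory sensory neurons, stood at 19.38 ± 0.12 in GFP+ and 19.37 ± 0.09 in GFP- samples (SD, n = 4), and did not pass (0.01 ± 0.14 SE, adjusted p = 0.988). Omp lay close to the highest value on each array (19.51 to 19.81), where saturation would hide a difference, so equal levels were not shown here or in the later comparisons. Of 22206 probe sets, 1295 were higher and 2189 lower in GFP+ cells (37.2% of the 3484 calls higher). This split followed the scaling: with each array centred on its median it was 8986 higher and 1750 lower (83.7% higher), and with quantile normalization 1972 and 2051 (49% higher). Centring moved the median of all probe sets from 0.14 to 0.50, and Omp then passed at 0.37 (adjusted p = 0.0418).

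Odorant receptors went both ways in vehicle. Among 1080 receptors, 389 were higher and 239 lower in GFP+ cells, or 440 and 269 when adjusted over the list alone; the median difference was 0.41 and stayed above 0 under every setting run. Olfr309 was 77.8-fold higher (6.28 ± 0.56 SE, adjusted p = 1.47e-07), Olfr536 was higher by 6.09 ± 0.30 and Olfr522 by 5.34 ± 0.34. At the other end, Olfr1507 was at least 94.2-fold lower (-8.54 ± 0.65), Olfr99 at least 112-fold lower (-7.71 ± 0.28) and Olfr1213 lower by a difference of -7.66 ± 0.56. Only 1 of 4 GFP+ arrays measured Olfr1213 above background, and it was 108-fold lower with the other arrays set to their background floor. Of 119 class I receptors, the family shared with fish, 40 were higher and 15 lower (45 and 23 adjusted over the list alone; adjusted p = 0.0138 by camera, adjusted p = 0.703 with an estimated correlation). Of 939 class II receptors 344 were higher and 215 lower (387 and 236 over the list alone), and neither this class nor all receptors together passed camera (adjusted p = 0.109 and 0.0919). The trace amine-associated receptors, a small separate family of olfactory receptors, had 6 of 15 members higher and 2 lower (4 lower with the pool as a random block), or 6 and 4 over the list alone; Taar9 was 10.6-fold higher (3.41 ± 0.50) and Taar4 7.95-fold higher (2.99 ± 0.33).

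Among 13 activity-dependent genes of olfactory neurons, 7 were higher and 2 lower in GFP+ cells in vehicle (8 and 2 adjusted over the list alone; camera adjusted p = 0.0255, and adjusted p = 0.214 with an estimated correlation). The 7 include S100a5, whose promoter drives the sorted reporter, so its direction follows from the sort. Lrrc3b was higher by 1.99 ± 0.44 and Pcp4l1 by 1.98 ± 0.34, while Calb2, which encodes the calcium buffer calretinin, was lower (-5.15 ± 0.23). The other lower member was Kirrel3 (-0.64, adjusted p = 0.00782 by limma), which is also the lower axon guidance gene. The list was fixed without a direction for each member, so a lower member need not go against activity. Camera tests for a shared direction alone. Pcdh10, an activity-dependent protocadherin, was 2.82-fold higher and passed narrowly (adjusted p = 0.0491, SE of the log2 difference 0.50), and its call was lost without any pool but odor replicate 4 (adjusted p = 0.0551 to 0.164), without both replicate 1 pools (0.171) and with the trended robust prior (0.0649). Kirrel2, an adhesion molecule of olfactory axons, had a difference of 1.17 ± 0.42 that did not pass (adjusted p = 0.068), but passed with the pool as a block (adjusted p = 0.0262 as a random and 0.00019 as a fixed term), with centred arrays (0.00932) and without vehicle replicate 4 (0.0427). Of 18 immediate early genes, which many cell types express, 14 were lower and 0 higher (camera adjusted p = 1.28e-16), in the same samples in which all 15 immune markers were lower (median -5.76), with Egr2 at -6.59 ± 0.34, Btg2 at -5.64 ± 0.37 and Egr1 at -4.94 ± 0.31. Egr2 and Btg2 were above background on 1 of 4 GFP+ arrays each, and had differences of -6.16 and -5.41 with the others at the floor. Of 19 axon guidance genes 6 were higher and 1 lower (8 and 1 over the list alone; camera adjusted p = 0.0541, adjusted p = 0.0465 with the pool as a random block, and adjusted p = 0.528 with an estimated correlation), among them Epha5, an ephrin receptor, at 1.21 ± 0.22. The olfactory signal transduction list had 5 of 21 members higher and 1 lower (7 and 1 over the list alone; adjusted p = 0.0264, and adjusted p = 0.528 with an estimated correlation), with the phosphodiesterase Pde1c at 0.94 ± 0.18. Its lower member was Grk3, a receptor kinase, at -1.26 ± 0.26 with both groups under background. Markers of mature neurons had 3 of 15 members higher and 0 lower (adjusted p = 0.0368, and adjusted p = 0.635 with an estimated correlation), led by Kcnmb3, a potassium channel subunit, at 1.71 ± 0.29. The adenylyl cyclase Adcy3 (0.50 ± 0.14), the chloride channel Ano2 (0.64 ± 0.18) and Epha7 (1.10 ± 0.32) passed too. Several lists share members, so their results are not independent. Adcy3 and Ano2 are on both the signal transduction and the mature neuron list, and Pcdh10 on both the activity-dependent and the axon guidance list. Cyp2g1 and Sult1c1 are on both the sustentacular and the xenobiotic list. Adcy3 lost its call without vehicle replicate 1, 2 or 4 (adjusted p = 0.114, 0.0730 and 0.103), Ano2 without 2 or 4 (0.0823 and 0.121), and Epha7 without 3 or 4 (0.0601 and 0.0735). With only the vehicle arrays in the fit all 3 lost it (0.0760, 0.0547 and 0.0798), as did Epha7 with array weights (0.0665) and Adcy3 without both replicate 1 pools (0.126).

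Markers of several other cell types of the mucosa were lower in GFP+ cells in vehicle. All 15 immune markers were lower (median -5.76, camera adjusted p = 2.00e-28), including the neutrophil granule gene Ngp at -11.27 ± 0.55, the macrophage lysozyme Lyz2 at -9.29 ± 0.49 and S100a8, at least 406-fold lower. Lcn2, a neutrophil and epithelial lipocalin, had a difference of -11.96 ± 0.62, and Spi1, a myeloid transcription factor, was at least 243-fold lower. Lcn2 and Lyz2 were above background on 1 and Ngp on 2 of 4 GFP+ arrays, and with the others at the floor their differences were -11.20, -9.11 and -11.05. Of 16 immature neuron markers 10 were lower (adjusted p = 4.16e-11), with Dpysl3 at -4.32 ± 0.33 and Sox11 at -2.92 ± 0.29, each above background on 2 of 4 GFP+ arrays (-4.16 and -2.89 with the others at the floor). Of 13 basal and progenitor markers 7 were lower (9 over the list alone, camera adjusted p = 3.97e-07), and Mki67, a proliferation marker, was at least 41.7-fold lower. The 6 that did not pass over all genes include all keratins on this list, so basal cells as a whole were not shown to be fewer. Sustentacular (supporting) cell markers had 8 of 14 members lower (adjusted p = 2.93e-07), with Krt18, a keratin, at least 6.70-fold lower and Sult1c1 at -3.35 ± 0.40 (3 of 4 GFP+ arrays above background, and -3.23 with the other at the floor). All 10 microvillous cell markers were lower (adjusted p = 5.00e-13), among them Foxi1 at -3.99 ± 0.33 (1 of 4 GFP+ arrays above background, and -3.39 with the others at the floor). All 3 erythroid markers were lower (adjusted p = 3.15e-05), with Slc4a1, the red cell anion exchanger, at -3.81 ± 0.41. Bowman gland and respiratory markers had 4 of 15 lower (camera adjusted p = 0.0044), and 11 did not pass. The largest differences were those of Ltf, which encodes lactoferrin, at least 84.5-fold lower, and of Sox9. Sox9 is also on the microvillous list. Ltf fell beside the immune markers (median -5.76), and an immune source of it was not told apart. The Bowman gland and respiratory list therefore does not stand for gland cells alone. Of 21 xenobiotic metabolism genes 9 were lower (adjusted p = 3.15e-05), with Gstm1 at -2.27 ± 0.22 and Cyp2g1 at -2.13 ± 0.37. The medians of the Bowman gland and the xenobiotic lists, both -0.35, turned to 0.01 with centred arrays. All of these lists, and the immediate early genes, also passed with an estimated correlation.

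**Figure D1:**
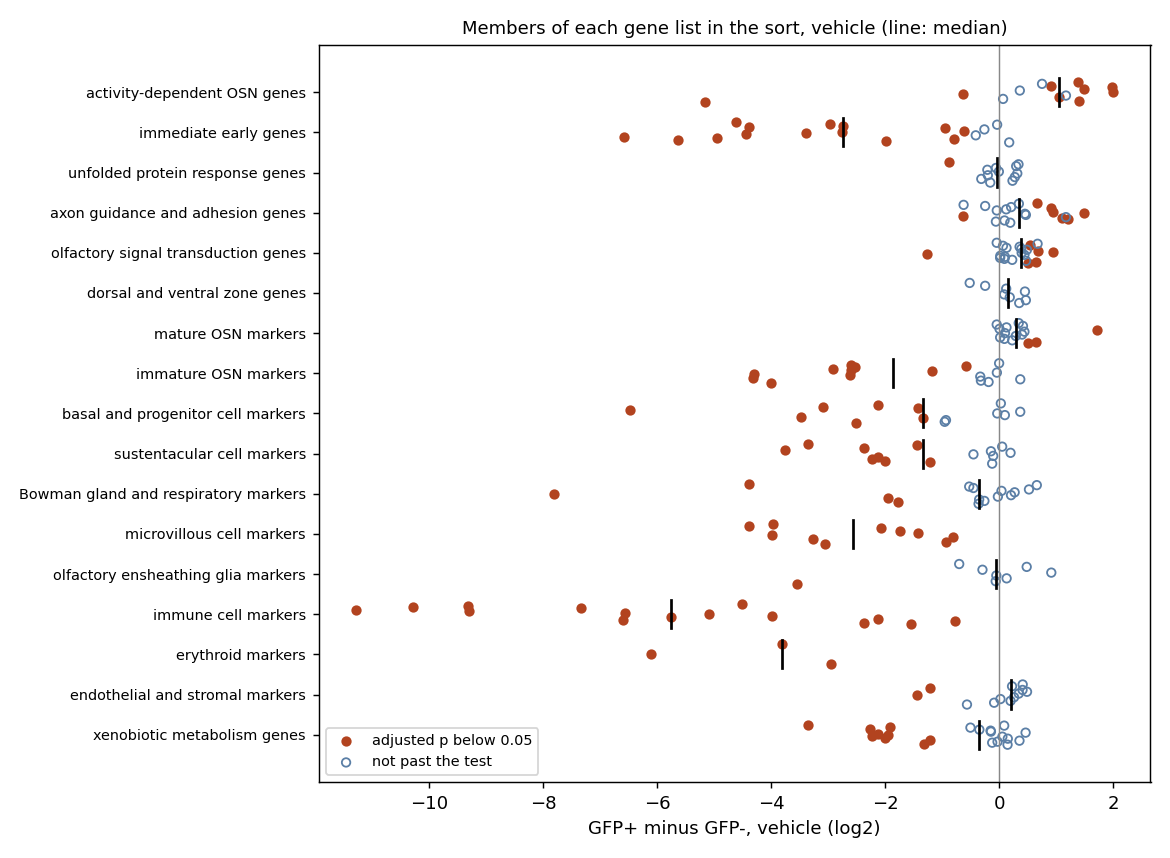
Difference between GFP+ and GFP- cells in vehicle (log2, x axis) for each measured member of 17 fixed gene lists (y axis), with filled points for members past adjusted p of 0.05 and a bar at each list's median. The immune markers all lie below 0, with a median of -5.76, while the activity-dependent genes have a median of 1.05.

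The remaining lists showed little separation in vehicle, and none of them passed camera. Counts adjusted over the list alone are given for lists where they differed. Of 12 unfolded protein response genes 1 was lower, the transcription factor Xbp1 at -0.87 ± 0.19, and 11 did not pass. Olfactory ensheathing glia markers had 1 of 8 lower (1 higher and 1 lower over the list alone), the 8 dorsal and ventral zone genes 0 in either direction, and the 3 sex-linked genes 0. With the pool as a random block 1 zone gene was higher and 1 lower, and 1 glia marker higher; as a fixed block 1 zone gene was lower and 1 sex-linked gene higher. Endothelial and stromal markers had 2 of 12 lower: Dcn, a matrix proteoglycan of fibroblasts, was at least 1.25-fold lower, and Pecam1 had a difference of -1.21 ± 0.28 with both groups under background. That list had a positive median (0.21) beside a negative mean (-0.08). Outside the lists and receptors, Fxyd2, a regulator of the sodium pump, was at least 9.08-fold higher in GFP+ cells, Ptprn, a protein of dense-core vesicles, 4.09-fold higher and the transcription factor Rfx4 3.53-fold higher. Ptprn was above background on 1 of 4 GFP- arrays, and 3.52-fold higher with the others at the floor.

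With 2-hexanone, the same question was asked of the fractions sorted from odor pools. S100a5 was 3.06-fold higher in GFP+ cells (1.61 ± 0.25 SE, n = 4 pools, adjusted p = 9.83e-05), and Omp did not pass (0.09 ± 0.14, adjusted p = 0.733; with centred arrays 0.44, adjusted p = 0.0196). Of 22206 probe sets 1175 were higher and 2124 lower (35.6% of 3299 higher), against 8534 and 1724 (83.2% higher) with centred arrays and 1855 and 2010 (48% higher) with quantile normalization. Of the 1080 receptors 391 were higher and 235 lower, or 456 and 265 adjusted over the list alone, with a median of 0.48. Olfr309 was again 86.3-fold higher (6.43 ± 0.56), Olfr536 higher by 6.27 ± 0.30 and Olfr60 by 5.18 ± 0.32. Olfr878 was at least 39.3-fold lower (-7.99 ± 0.42) and Olfr1384 at least 86.1-fold lower (-7.56 ± 0.33). All receptors together and class II passed camera (adjusted p = 0.0304 and 0.0233), but not with an estimated correlation (adjusted p = 0.694 and 0.686). Class I had 35 of 119 members higher and 15 lower (41 and 20 over the list alone), and class II 351 of 939 higher and 211 lower (408 and 236). Trace amine-associated receptors had 4 of 15 higher and 2 lower (8 higher with the pool as a random block), or 8 and 4 adjusted over the list alone, with Taar4 9.40-fold higher (8.70-fold with 2 of 4 GFP- arrays at the floor) and Taar9 7.83-fold higher.

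Activity-dependent genes in odor had 7 of 13 members higher, S100a5 again among them, and 2 lower (8 and 2 over the list alone; adjusted p = 0.0149, and adjusted p = 0.17 with an estimated correlation). Lrrc3b was higher by 2.25 ± 0.44, Pcp4l1 by 2.23 ± 0.34 and Pcdh10 by 2.16 ± 0.50. Immediate early genes had 15 of 18 lower and 1 higher (adjusted p = 6.20e-17), beside immune markers with a median of -5.48. The higher member, Npas4, was singled out after its values were seen; it had a difference of 1.04 ± 0.30 with both groups under background, and lost its call without odor replicate 2, 3 or 4 (adjusted p = 0.108, 0.11 and 0.0809) or with only the odor arrays in the fit (0.0506). All 15 immune markers were lower (median -5.48, adjusted p = 8.83e-29), with Ngp at -11.21 ± 0.55 (3 of 4 GFP+ arrays above background, and -11.09 with the other at the floor). All 10 microvillous and all 3 erythroid markers were lower, as were 9 of 16 immature neuron, 8 of 13 basal, 9 of 14 sustentacular, 4 of 15 Bowman gland and 9 of 21 xenobiotic metabolism genes. Over the list alone, 10 immature neuron markers were lower, and 1 xenobiotic gene was higher and 9 lower. Each of these lists passed camera, and only the Bowman gland list lost its call with an estimated correlation (adjusted p = 0.0578). Signal transduction genes had 4 of 21 higher and 1 lower, and mature neuron markers 3 of 15 higher and 0 lower (adjusted p = 0.02 and 0.0134, and adjusted p = 0.505 for both with an estimated correlation). Over the list alone these were 5 and 1, and 4 and 0. The other lists did not pass camera: axon guidance genes had 5 of 19 higher and 1 lower, unfolded protein response genes 0 and 1 of 12, zone genes 1 and 0 of 8, ensheathing glia markers 1 and 1 of 8, endothelial markers 1 and 3 of 12, and sex-linked genes 0 of 3. Over the list alone the axon guidance genes had 9 and 1, zone genes 2 and 1, ensheathing glia markers 1 and 2, and endothelial markers 4 and 3. With the pool as a random block 2 zone genes were higher and 1 lower, 2 glia markers lower and 1 xenobiotic gene higher. As a fixed block 8 axon guidance genes were higher, 2 glia markers lower, and 1 xenobiotic and 1 sex-linked gene higher. The Bowman gland median, -0.12, turned to 0.23 with centred arrays. Fxyd2 was at least 8.13-fold higher, Ptprn 4.86-fold higher (3.31-fold with 3 of 4 GFP- arrays at the floor) and Ly6e, a surface protein gene of many cell types, 608-fold lower.

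The receptors that separated the fractions overlapped strongly between treatments. The log2 differences of the 2 comparisons share no array. Their calls do share a residual variance per gene, taken from a single fit over all arrays of both treatments. The overlap of calls is therefore not that of independent tests. Of the receptors, 408 were higher and 243 lower in GFP+ cells in both treatments, and 0 were higher in the one and lower in the other. The sort difference in odor correlated with that in vehicle across the 1080 receptors (Pearson r = 0.976, Spearman rho = 0.966), which are not independent replicates. Over all probe sets 673 were higher in both, against 68.5 for independent lists, and 1859 lower in both, against 209.4.

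**Figure D2:**
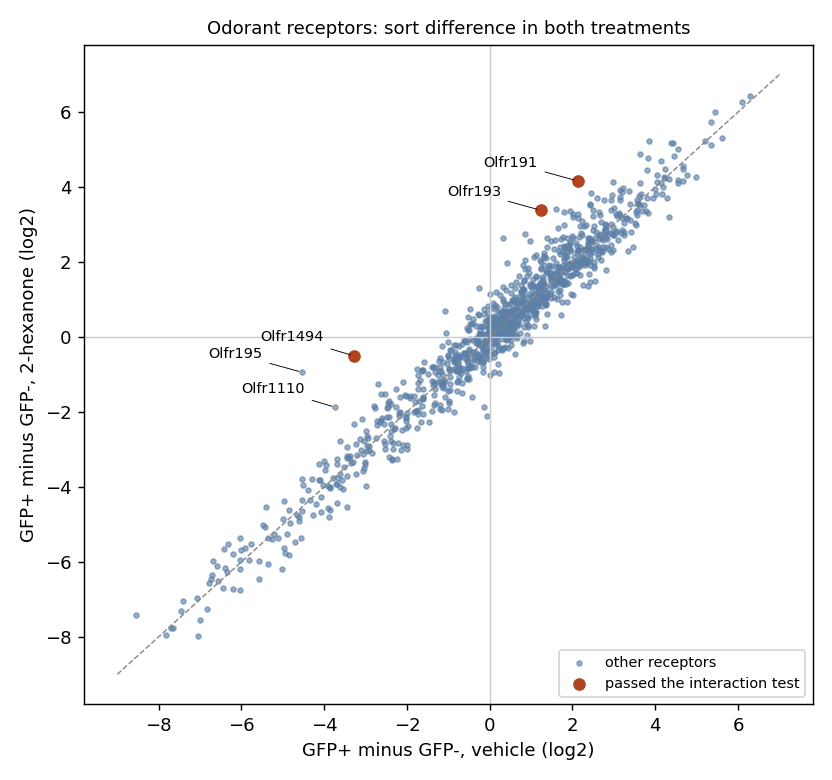
Difference between GFP+ and GFP- cells (log2) of each of 1080 odorant receptors in vehicle (x axis) and with 2-hexanone (y axis), with larger points for receptors past the test of the change in that difference and a dashed line of equal values. Olfr191, Olfr193 and Olfr1494 lie above the line, by 2.04, 2.15 and 2.77.

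The next comparison asked which transcripts 2-hexanone changed within GFP+ cells. Receptor Olfr1494 rose 7.02-fold, from 7.64 ± 0.60 in vehicle to 10.45 ± 0.39 in odor (SD, n = 4; log2 difference 2.81 ± 0.27 SE, adjusted p = 0.000128). Camk2n1, an inhibitor of the kinase CaMKII, rose from 5.95 ± 0.73 to 8.76 ± 0.70 (2.81 ± 0.35 SE, adjusted p = 0.00268). Only 1 of 4 vehicle arrays measured it above background, and the rise was 4.57-fold with the others at the floor. For both genes all 4 odor arrays lay above all 4 vehicle arrays. These were the 2 calls among 22206 probe sets by limma; 869 had an unadjusted p under 0.05, where chance alone gives 1110. Adjusted over the list alone, 3 of 1080 receptors rose and 0 fell: Olfr1494 (adjusted p = 6.24e-06), Olfr195 from 5.55 to 8.90 (3.35 ± 0.55, adjusted p = 0.00577) and Olfr1110 from 8.08 to 10.09 (2.01 ± 0.39, adjusted p = 0.023). Olfr195 was above background on 2 of 4 vehicle GFP+ arrays, and its difference was 2.24 with the others at the floor. These receptors were lower in GFP+ than in GFP- cells in vehicle, by log2 differences of -3.28 ± 0.27, -4.53 ± 0.55 (-3.41 with 2 of 4 GFP+ arrays at the floor) and -3.73 ± 0.39, a comparison made after their values were seen and sharing the vehicle GFP+ arrays. Olfr195 lost its call without vehicle replicate 3 (adjusted p = 0.0638), and Olfr1110 without odor replicate 2 or vehicle replicate 1, 2, 3 or 4 (adjusted p = 0.0819, 0.0503, 0.0777, 0.187 and 0.0853). With only the GFP+ arrays in the fit, Olfr1494 alone passed, and Camk2n1 (adjusted p = 0.227), Olfr195 and Olfr1110 (both 0.139) did not. Without both replicate 1 pools Olfr195 and Olfr1110 did not pass either (0.0613 and 0.0835). The high percentile of the negative control rows lay at 8.53 to 9.47 on odor GFP+ arrays. The odor means of Camk2n1 and Olfr195 fell within that range, and those of Olfr1494 and Olfr1110 above it. On vehicle GFP+ arrays it lay at 8.57 to 9.31, above the vehicle means of all 4 genes.

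Other receptors did not pass in GFP+ cells in the planned fit: Olfr175 had a difference of 1.38 ± 0.31 (adjusted p = 0.0817) and Olfr193 of 1.10 ± 0.26 (adjusted p = 0.112). Both passed with the trended robust prior (0.0304 each) and with the replicate number as a block (0.0402 each), and Olfr175 without odor replicate 2 (0.0487). S100a5 had a difference of 0.31 ± 0.25 and Omp of 0.08 ± 0.14, and neither passed. No member of the other lists passed over all genes. Adjusted over the list alone, 1 activity-dependent gene passed, Pcdh10 at 2.65 ± 0.50 (adjusted p = 0.000629, against 0.164 over all genes), as it did among the axon guidance genes. Among the trace amine-associated receptors 1 passed that way, Taar5 at -0.89 ± 0.24 (adjusted p = 0.0245), with both groups under background, named after its value was seen. Mki67 (-1.32 ± 0.43), Dcn (0.71 ± 0.22) and Npas4 (0.67 ± 0.30) did not pass, with both groups under background. As whole lists, sustentacular markers had a median of 0.32 (camera adjusted p = 0.00278, and adjusted p = 0.315 with an estimated correlation), and xenobiotic metabolism genes of 0.17 (adjusted p = 0.0473, and adjusted p = 0.315). Cbr2, a carbonyl reductase on both of these lists, had a difference of 0.78 ± 0.29 and Cyp2g1 of 0.72 ± 0.37, neither passing. Class I receptors had a median of -0.20 (adjusted p = 0.000476, and adjusted p = 0.916 with an estimated correlation), and 0 of 119 passed alone.

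**Figure D3:**
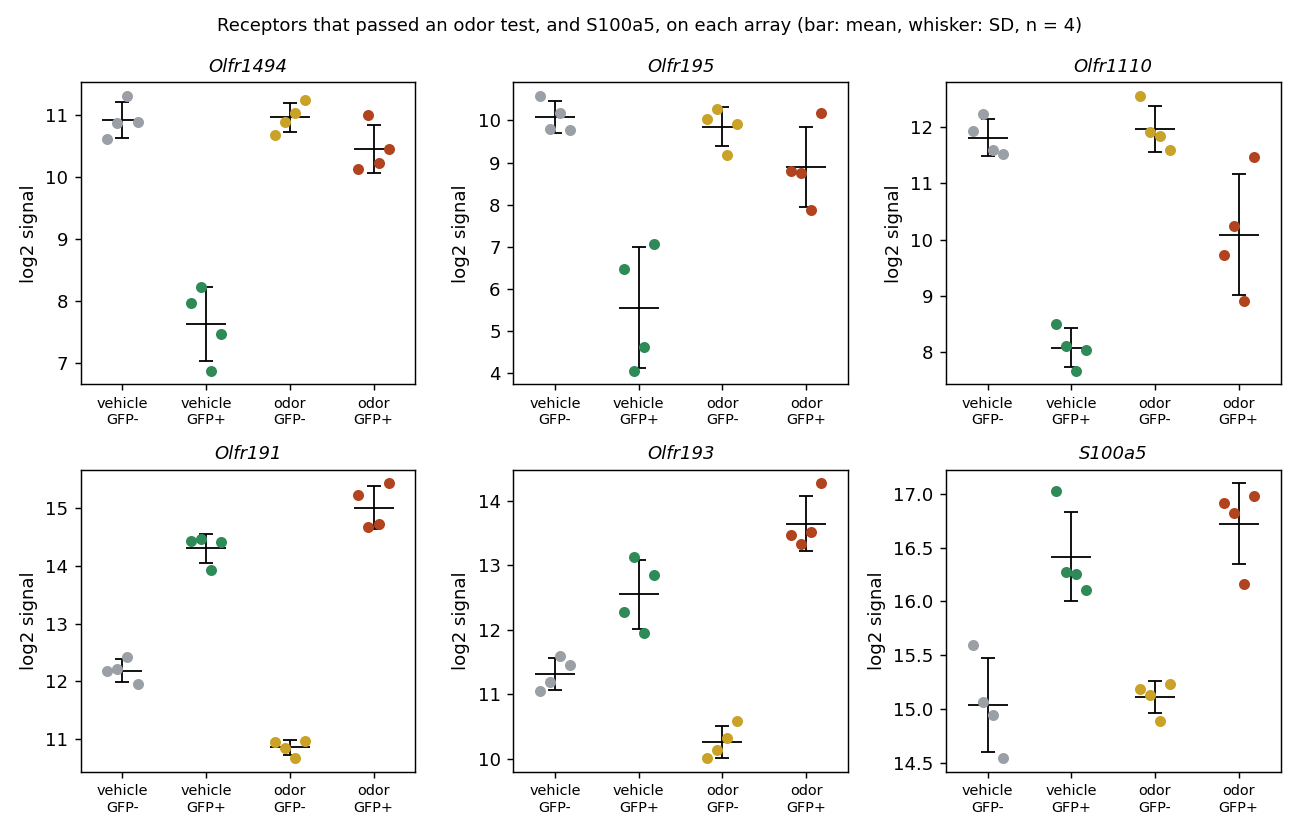
Log2 signal on each array (y axis) by group (x axis) for 5 receptors that passed a test of odor and for S100a5, with bars at the mean and whiskers of 1 SD (n = 4). Olfr1494 averages 7.64 in vehicle GFP+ samples and 10.45 in odor GFP+ samples, and Olfr191 averages 12.19 and 10.85 in the GFP- samples of vehicle and odor.

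Within GFP- cells, a single odorant receptor fell with 2-hexanone. Olfr191 went from 12.19 ± 0.19 to 10.85 ± 0.13 (SD, n = 4; log2 difference -1.33 ± 0.20 SE) when adjusted over the list alone (adjusted p = 0.00316), with all 4 odor arrays below all 4 vehicle arrays. It did not pass over all genes (adjusted p = 0.065). By limma 0 of 22206 probe sets passed, and 547 had an unadjusted p under 0.05 against 1110 by chance. Olfr1199 (-1.68 ± 0.36, or -1.61 with 1 of 4 odor arrays at the floor, adjusted p = 0.126, and 0.0407 with array weights) and Olfr193 (-1.05 ± 0.26, adjusted p = 0.274) did not pass over the receptors. S100a5 (0.07 ± 0.25), Omp (-0.01 ± 0.14), Cbr2 (0.61 ± 0.29) and Aldh1a7 (0.55 ± 0.23, under background in both groups) did not pass. Adjusted over the list alone, Pcdh10 passed among the activity-dependent and the axon guidance genes (1.99 ± 0.50, adjusted p = 0.0112 among the former), and Taar8a among the trace amine-associated receptors (0.93 ± 0.26, adjusted p = 0.0355, under background in both groups), the latter named after its value was seen. The receptors and the gene called in GFP+ cells were looked up after their values were seen, and none passed here: Olfr1494 had 0.04 ± 0.27, Olfr195 -0.23 ± 0.55, Olfr1110 0.16 ± 0.39 and Camk2n1 1.10 ± 0.35. Sustentacular markers again had a positive median, 0.31 (camera adjusted p = 0.00143, and adjusted p = 0.308 with an estimated correlation), in the same direction as in GFP+ cells.

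The last comparison, for which the assay is built, asked whether the difference between GFP+ and GFP- cells depended on the odor. It did so for 3 receptors when adjusted over the list alone, all toward GFP+ cells: Olfr191, Olfr193 and Olfr1494. For Olfr191 the difference grew from 2.12 ± 0.20 in vehicle to 4.16 ± 0.20 in odor (change 2.04 ± 0.28 SE, adjusted p = 0.000565). For Olfr193 it grew from 1.23 ± 0.26 to 3.38 ± 0.26 (change 2.15 ± 0.37, adjusted p = 0.00587). For Olfr1494 it went from -3.28 ± 0.27 to -0.51 ± 0.27 (change 2.77 ± 0.38, adjusted p = 0.000565), and the odor difference did not pass (adjusted p = 0.104). In each case all 4 odor pools had a higher GFP+ to GFP- difference than all 4 vehicle pools. Over all genes Olfr191 and Olfr1494 were the 2 calls by limma (both adjusted p = 0.0116), with 650 probe sets at an unadjusted p under 0.05 against 1110 by chance. With any 1 of the 8 pools left out, Olfr191 no longer passed over all genes, and Olfr1494 passed there only without vehicle replicate 1 or 2. Both still passed over the receptors, with changes of 1.84 to 2.16 and 2.39 to 2.99. With the pool as a random block 3 genes and 5 receptors passed, adding Olfr193 over all genes and Olfr195 (3.58 ± 0.78, adjusted p = 0.024) and Olfr371 (-2.04 ± 0.47, under background in all groups, adjusted p = 0.0422) over the receptors. Olfr195 was above background on 2 of 4 vehicle GFP+ arrays. With the others at the floor its vehicle sort difference moved from -4.53 to -3.41, which would lessen its change. With the pool as a fixed block 0 genes and 4 receptors passed, adding Olfr195 (adjusted p = 0.0433). In the fit without a block Olfr195 and Olfr371 did not pass (adjusted p = 0.0648 and 0.0941). Olfr195 also passed with the replicate number as a block (0.0226), array weights (0.0305) or vehicle replicate 4 left out (0.0110), and Olfr371 with vehicle replicate 2 left out (0.00852).

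By the rule fixed beforehand, a receptor responding to 2-hexanone had to pass this test and that within GFP+ cells, and to be higher in odor GFP+ than in odor GFP- cells. In all 0 receptors met the rule, while 1, Olfr193, met it with the trended robust prior and with the replicate number as a block. Olfr1494 passed both tests but was not higher in odor GFP+ cells (-0.51 ± 0.27), and Olfr191 and Olfr193 were higher there but did not pass within GFP+ cells (0.71 ± 0.20 and 1.10 ± 0.26, adjusted p = 0.219 and 0.112). S100a5 (0.23 ± 0.35), Omp (0.09 ± 0.20), Camk2n1 (1.71 ± 0.49), Olfr1110 (1.85 ± 0.54), Pcdh10 (0.66 ± 0.70) and Npas4 (1.07 ± 0.43) showed no change of the sort difference that passed. None of the 22 gene sets passed for this change.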

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

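Tests of a hybridisation effect, a cross-hybridising transcript, a shared gene cluster and the sex ratio of pools were chosen after the results were seen. Among 215 gene and group pairs, 16 had 1 sample of 4 apart from the rest, where chance gives 10.8 (1 in 20); the measure is the gap to the nearest sample over the range, above Dixon's critical value for 4 samples. The 16 fell 4 to each replicate number. In vehicle GFP+ samples, Omp was low in replicate 3 (19.20, nearest 19.42, ratio 0.893), Taar4 high in 2 (10.80, nearest 10.26, ratio 0.847) and Retnlg high in 4 (5.70, nearest 4.62, ratio 0.911). Gng8 was low in 4 (3.49, nearest 5.33, ratio 0.842), Ltf high in 2 (5.96, nearest 4.85, ratio 0.852) and Car1 low in 3 (2.68, nearest 4.24, ratio 0.908). Slc4a1 was high in 2 (7.71, nearest 7.31, ratio 0.929), Olfr191 low in 3 (13.92, nearest 14.41, ratio 0.903) and Cbr2 low in 4 (9.26, nearest 10.54, ratio 0.927). In vehicle GFP- samples, Olfr1213 was low in 1 (12.12, nearest 13.49, ratio 0.872), Egr2 high in 2 (13.30, nearest 12.52, ratio 0.905), Ano2 high in 1 (17.44, nearest 17.01, ratio 0.915) and Foxi1 high in 1 (10.75, nearest 9.69, ratio 0.858). In odor, Olfr677 was high in GFP+ replicate 1 (4.99, nearest 3.49, ratio 0.856), Pcdh10 high in GFP+ replicate 4 (12.86, nearest 11.46, ratio 0.849) and Olfr371 low in GFP- replicate 3 (4.17, nearest 5.20, ratio 0.858). The values of Retnlg, Gng8, Ltf, Car1, Olfr677 and Olfr371 lay under background on all arrays of their group, so these gaps are not measured levels. The difference between fractions changed with odor, by its own test, for Olfr191 (2.04), Olfr193 (2.15) and Olfr1494 (2.77).

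Receptors of families MOR183 and MOR184, which hold Olfr191, Olfr193 and Olfr195, tended to be more enriched in GFP+ cells under odor, a pattern noticed from the top genes: 14 of 15 members had a change above 0 (median 1.13), 9 with an unadjusted p under 0.05. They had the 2 highest mean t values of 121 families, 3.27 and 2.37, and 1 of 35 splits of the pools gave a highest family mean t as high as 3.27, the real one, the highest of the others being 2.26. Each split also stood for its mirror, with odor and vehicle exchanged, although this measure changes with that exchange. The mirrors were not compared, so the splits do not exclude chance here. A single transcript read by all probe sets is argued against by the spread of the vehicle sort difference (SD 1.88, largest SE 0.551), although a mix stays open, and a shared gene cluster by its 10 MOR182 receptors (-0.39 to 0.49, median -0.051); 9 of these lie past the families' stretch, so a local stretch is not separated from family. Olfr193 also belongs to MOR113, and its count under MOR183 was adopted after it was seen to pass; without it the median was 1.12, and by first-listed family MOR183 had a mean t of 2.84. Without Olfr191, Olfr193 and Olfr195, which drew attention to the families, 11 of 12 members lay above 0 (median 1.08); p-values against the neighbours are not given, since the families were picked from these values. A response of neurons with these receptors to 2-hexanone may underlie the pattern, as a hypothesis found and tested on the same data.

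Arrays of replicate 1 stood apart from the others on the first residual component (21.6% of residual variance), at -33.7 to -43.0 against -1.84 to 36.4. The control rows, which read no mouse gene, separated them too: 4 of 4 lay outside the range of the other 12 on their first component (48.3% of residual variance), so array processing may have contributed. The sex ratio of the pools is argued against, since 1 of 4 had a Y-linked mean outside the range of the others. No other biological explanation was tested.

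The number of calls was compared with that of all 35 splits of 8 samples into 4 and 4. For the sort, only the real split gave as many calls. The genes were 3484 in vehicle and 3299 in odor (highest other 0 in each). The receptors were 709 (highest other 105) and 721 (highest other 1). The fractions of a pool are paired, and beside the real split only 7 part all 4 pairs, too few to exclude chance by themselves. These 7 gave 0 genes and 0 receptors, and the 105 came from a split parting 2 pairs. A split that mixes the fractions also holds the sort difference in its spread, which lowers its count of genes. Chance cannot be excluded for odor in GFP+ cells, where 4 splits gave 2 genes or more (highest other 6) and 8 gave 3 receptors or more (highest other 50). Nor can it for the change of the sort difference (2 genes: 2 splits, highest other 3; 3 receptors: 2 splits, highest other 12). Counts of 0 are matched by all 35 splits whatever the data, so the splits say nothing of the 0 genes in GFP- cells (highest other 3), the 0 receptors meeting the rule (highest other 1) or the 0 gene sets for the change (highest other 9). The gene set counts were 13 and 14 in the sorts (6 and 4 splits, highest other 16 in each). They were 3 in GFP+ cells (16 splits, highest other 7) and 1 in GFP- cells (30 splits, highest other 14), and chance is excluded for neither odor comparison. For the sorts these counts cannot decide on chance, since other splits called up to 16 sets while calling 0 genes. A split that mixes the fractions unevenly still holds part of the sort difference. Within GFP- cells no sort difference is mixed in, and a split other than the real one still called 14 sets. The counts are made of the same camera calls given for each list, without an estimated correlation. Those calls therefore do not exclude chance for the sorts by themselves. Calls with an estimated correlation, given with the results, are not part of these counts. The 50 and the 12 receptors came from parting replicates 1 and 3 from 2 and 4, several times the real counts, which points to a structure that follows the numbers. The mean of Y-linked genes parts the same way, at 6.58 to 7.55 in replicates 1 and 3 and 8.32 to 9.78 in 2 and 4 of both treatments, so the sex ratio of the pools stays open for this split and was not tested. With the number as a block 7 receptors passed in GFP+ cells and 5 for the change.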

How the results depend on the processing

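Arrays measured signal over background, which limited dim genes. In 1146 of 3484 calls in vehicle and 1013 of 3299 in odor, higher and lower together, all arrays of the dimmer fraction lay under the floor. Calls with both fractions under it are not counted there. Causes were not tested, except that fits on fewer arrays have less power by construction; the batch term and leaving out both replicate 1 pools were chosen after seeing the data. Over 134 gene and contrast pairs, 2765 values under alternatives were computed; 2691 kept direction and call, 38 lost a call, 21 gained one, 13 changed sign and 2 came to 0. Centring moved the sort counts to 10736 and 10258. Without 1 pool they ranged from 2487 to 3410 and 2376 to 3383, receptors from 659 to 724 and 673 to 745, and set counts from 10 to 16 and 13 to 15. Beyond what is given with the results, the pool block changed no call of a named gene or gene set, and moved no count of genes, receptors, sets or list members by over 1.5 times; sets were run with the random block alone.

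Genes called for odor in GFP+ cells numbered 5 with the replicate number as a block, 1 with only the arrays compared and 2 to 3 without 1 pool; receptors numbered 6 with the trended robust prior, 7 with the number block, 1 with only the arrays compared, 1 without both replicate 1 pools, and 1 (without vehicle replicate 3) to 5 (without odor replicate 2) without 1 pool. In GFP- cells 1 gene passed over all genes in several settings, not the same gene in each. It was Olfr191 with the trended robust prior, either quantile normalization, the lowest 40% left out or array weights, and Pcdh10 with the number block. With any 1 pool left out 0 passed. For the change of the sort difference, the pool as a fixed block and leaving out both replicate 1 pools gave 0 genes, and leaving out 1 pool 0 to 1 (1 without vehicle replicate 1 or 2). Receptors there numbered 5 with the pool as a random block or the number block, and 3 to 6 without 1 pool (6 without vehicle replicate 4). Olfr193 met the 3-part rule with the trended robust prior and the number block, 1 receptor each, and 0 did without any pool. Olfr191 in GFP- cells and the change of Olfr193 lost their calls without both replicate 1 pools (adjusted p = 0.0997 and 0.109). With an estimated correlation 8 sets passed for the sort in odor and 0 for odor in either fraction. Leaving out 1 pool gave 1 to 4 sets in GFP+ cells (1 without odor 3, odor 4, vehicle 1 or vehicle 4), 1 to 6 in GFP- cells (5 without odor 1, 2 without odor 2 or vehicle 1, 6 without vehicle 4) and 0 to 2 for the change (1 without vehicle 1, 2 without vehicle 4), where leaving out both replicate 1 pools gave 1.

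Values that changed sign or came to 0 belonged to genes that did not pass. With quantile normalization over all arrays or within fractions, Omp was 0 in GFP+ cells, 0.047 and 0.049 in GFP- cells, and -0.047 and -0.049 for the change. Without 1 pool, Omp in the vehicle sort ranged from -0.042 to 0.055, and in GFP- cells S100a5 from -0.091 to 0.26, Omp from -0.054 to 0.031, Olfr1494 from -0.059 to 0.17 and Olfr1110 from -0.038 to 0.29; Olfr1110 was -0.0013 without both replicate 1 pools.

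Replicate numbers across treatments were not taken as pairs, since the labels do not say that they are. Deviations of odor and vehicle samples of the same number correlated at 0.419, 0.0996, 0.214 and 0.0492 in GFP+ cells. In GFP- cells they correlated at 0.354, 0.0841, 0.031 and 0.214. These values lie within those between the fractions of a pool (0.0136 to 0.425). Of 8 odor arrays, 7 correlated best with their own number, a hint from the data of a structure shared by number. The fit behind the results has no term for the number. With that number as a block Pcdh10 passed in GFP+ and GFP- cells (adjusted p = 2.86e-05 and 0.0012).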

Other observations

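Other receptor families, singled out after their values were seen and not tested one by one, had all or most members on one side of 0 in the change of the sort difference with odor. All 7 measured MOR165 members lay above 0 (median 1.20, mean t 1.62), as did all 5 of MOR251 (median 0.76, mean t 1.67), the family of Olfr309. Of 8 MOR266 members, which include Olfr1494, 6 lay above 0 (median 0.38). Others lay on the other side: of 11 MOR31 members 0 lay above 0 (median -0.49, mean t -0.94), as did 0 of 8 in MOR34 (median -0.41, mean t -0.88), 0 of 5 in MOR219 (median -0.20) and 0 of 3 in MOR26 (median -0.52). The positive mean t values given here lie below 2.26, the highest of any family in the other splits of the pools, with mirrored splits not compared.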
